A study of Bifidobacterium longum NCC2705 with 3 samples.

How the data were processed

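The samples were 3 libraries of total RNA from wild-type Bifidobacterium longum NCC2705, sampled from MRS culture at an optical density of 0.5 at 660 nm. Per the labels' protocols, ribosomal RNA was removed with the Ribo-Zero kit, the RNA was reverse transcribed, and standard Illumina libraries were sequenced on a MiSeq. CASAVA is named in the submitters' processing notes. The aligner, the counting tool, the treatment of reads that map to several places, the use of strand in counting and the genome build are not given in the sources used here.

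The authors deposited a table of RPKM values, per the file headers, with 1726 protein-coding genes as rows and a column per library, so replicates were not pooled. Columns were matched to samples by the sample numbers in their names and labels. The table pairs each gene name with a product, a protein identifier and a position, and positions are given here as the table gives them, counted from 1. All coding lengths were multiples of 3, so the gene models hold coding sequence only. Genes of ribosomal and transfer RNA were not analysed here, and the lists fixed for them had no members.

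RPKM multiplied by coding length was a whole multiple of 1 step in each library, within a tolerance of 0.01 reads, for 100% of the genes with a position. This gave the reads behind each value. A position could not be read for 3 genes (fabG, BL0512 and BL1538), and their lengths were solved by setting the library sizes behind the steps, 2138109, 5031491 and 4536302 reads in libraries 1, 2 and 3, equal to the reads of all listed genes, so that the reads sum to these sizes by construction. The solved lengths were whole, 741, 804 and 546 bases, which the solution did not force, and RPKM was on this ground taken as scaled to the reads of the listed genes alone, so that a gene that takes a large share of the reads lowers the RPKM of all others. At the median coding length, a count of 0 (allowing up to 3 reads) corresponds to at most 1.45, 0.617 and 0.685 RPKM in the 3 libraries. The 95% intervals of read shares are Wilson intervals, and they and the limits for a count of 0 cover counting error only, since the reads carry no molecular identifiers. No count model was fitted to the recovered reads, since one was planned only for deposited counts. The recovered reads served for shares, intervals, limits for a count of 0, counts of genes under 10 reads, ranks by reads, a chi-square comparison of each pair of libraries over genes with at least 10 reads in the pair, and thinning to equal depth.

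Levels are means with SDs over the 3 libraries, and tests used the mean of log2(RPKM + 1). A fold difference on that scale understates differences of low genes. There is 1 condition, so no comparison between conditions was possible. Gene lists were fixed before the data were examined, by gene symbol and words in the product name. Of 23 lists, 20 with at least 3 members were tested. Those for ribosomal RNA, transfer RNA and toxin-antitoxin modules had no members once false word matches had been removed. After the data were seen, 14 false word matches were taken out (for instance folD, matched as a regulator through part of the word tetrahydrofolate), and the lists as first matched were kept as an alternative. The median of the list's members minus the median of all other genes was set against 10000 random lists of the same size, two-sided, with Benjamini-Hochberg adjustment over the 20 lists at a threshold of 0.05. On real levels in shuffled order, 5.26% of simulated lists of up to 100 genes passed the unadjusted threshold with no shift, and 16.3%, 61.1% and 85.3% passed with shifts of 0.5, 1 and 2 on the log2 scale (190 lists each over 1726 genes). The simulated members were random genes, so these rates do not describe lists whose members are neighbours of like level. The recovery of reads was tested on simulated RPKM of 1723 genes and returned 100% of them exactly.

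Adjacent genes were compared by Spearman's rho with 10000 permutations of the gene order, and the difference between same-strand and opposite-strand pairs by 10000 permutations of the pairs. Position on the chromosome was tested by rotating expression along the gene order, where the smallest p is 0.00058. On shuffled levels with the real strands of 1723 genes, 5% of 100 simulations passed with no shift between strands and 100% with a shift of 0.5 on the log2 scale. The shift was set between the plus and minus strands, not between leading and lagging genes. Shuffling also removed the likeness of neighbouring genes that rotation keeps. These rates therefore do not give the error rate or the power of the position tests on the real gene order. The terminus was planned from GC skew, but no genome was used here, and it was placed opposite dnaA instead. Comparisons that need the genome sequence (a promoter hexamer, ribosome binding sites and codon usage) were planned and not run. The related strain of assembly ASM19655v1 was used only for gene names and for which genes neighbour each other, and 273 genes were matched to it by a symbol that occurs once in each strain.

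The genes named were chosen by a rule set before the data were examined: the 20 highest genes, the 2 highest and the 1 lowest member of each list, the 5 genes with the largest SD of log2 level between libraries among genes above the median level, and a fixed set (xfp, ldh, gap, eno, tuf, groEL, groES, dnaK, hup, lnpA, lacZ, fusA, rpoB, rpoA, ftsZ, recA, gyrA and dnaA). Of the fixed set, xfp was taken as the row whose product is phosphoketolase, ldh as ldh1 and ldh2, and gyrA as gyrA1, and lnpA was not matched to a row. The genes around BL1417 and BL0278, tal and ackA in the plot of fermentation genes, BL1480 and fabG were chosen after their values were seen. So were further genes in the other observations. Alternatives changed the pseudocount (0.1 or 10), left out genes at or below the 10th percentile of the mean level or each library in turn, used means for medians, rotation for random lists, a background without hypothetical proteins, size factors from medians of ratios, or a common sum per library, and left out ribosomal proteins and translation factors. Those added after the data were seen gave libraries 2 and 3 together the weight of 1 library, kept the lists as first matched, moved the terminus, left out BL1417, or kept genes of 300 bases or more. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.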

Results

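RNA was sequenced from wild-type Bifidobacterium longum NCC2705, a strain of a human gut bacterium that ferments sugars through the bifid shunt. The cells were grown in MRS, a rich medium used for lactic acid bacteria and bifidobacteria, and were taken at an optical density of 0.5 at 660 nm, and ribosomal RNA was depleted. The data comprised 3 libraries of this single condition (libraries 1, 2 and 3), so the comparisons made here were between libraries, between groups of genes within the libraries, and between positions on the chromosome. The deposited table gave reads per kilobase of coding sequence, scaled to the reads of each library (RPKM), for 1726 protein-coding genes in each library. Reads per gene read back from these values summed to 2138109, 5031491 and 4536302 in libraries 1, 2 and 3. The median gene held 428.5, 1029 and 895.5 reads respectively. The submitters used fragment depth to place transcription start sites, which were not analysed here.

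The question of how closely the libraries resembled each other was answered first, since their spread is the error of every level below. Libraries 2 and 3 were nearly alike, and library 1 stood apart from both. Across genes, Pearson's r of log2(RPKM + 1) was 0.996 between libraries 2 and 3, 0.921 between libraries 1 and 2, and 0.923 between libraries 1 and 3. A difference of more than 2-fold separated libraries 2 and 3 at 8 genes, libraries 1 and 2 at 321 genes, and libraries 1 and 3 at 310 genes. The chi-square per degree of freedom of the reads was 5.15 for libraries 2 and 3, above the value of 1 that counting noise alone gives, so they were not merged as a library deposited more than once, although this does not show that they came from separate RNA. It was 305 for libraries 1 and 2 and 288 for libraries 1 and 3. The median gene had an SD of log2(RPKM + 1) of 0.30 over the 3 libraries. The labels do not say whether the libraries came from separate cultures, so the SDs given here measure only the spread between these libraries, which may be technical. Genes are not independent replicates, and correlations across genes carry no p-value.

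Among genes above the median level, the 5 with the largest spread between libraries were BL1622, BL0814, BL0033, BL0562 and BL0813. BL1622, a hypothetical protein gene at 2030169 to 2030378 on the minus strand, had 31690, 1607 and 1313 RPKM in libraries 1, 2 and 3. The hypothetical protein genes BL0814 and BL0813, which lie side by side on the minus strand, had 4573, 358 and 559 RPKM and 1272, 203 and 222 RPKM in the same order. BL0562, also of unknown function, had 1552, 254 and 239 RPKM. The opposite direction was seen at BL0033, a solute-binding protein of a sugar ABC transporter at 41952 to 42935, with 366 RPKM in library 1, 2815 in library 2 and 2736 in library 3.

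**Figure D1:**
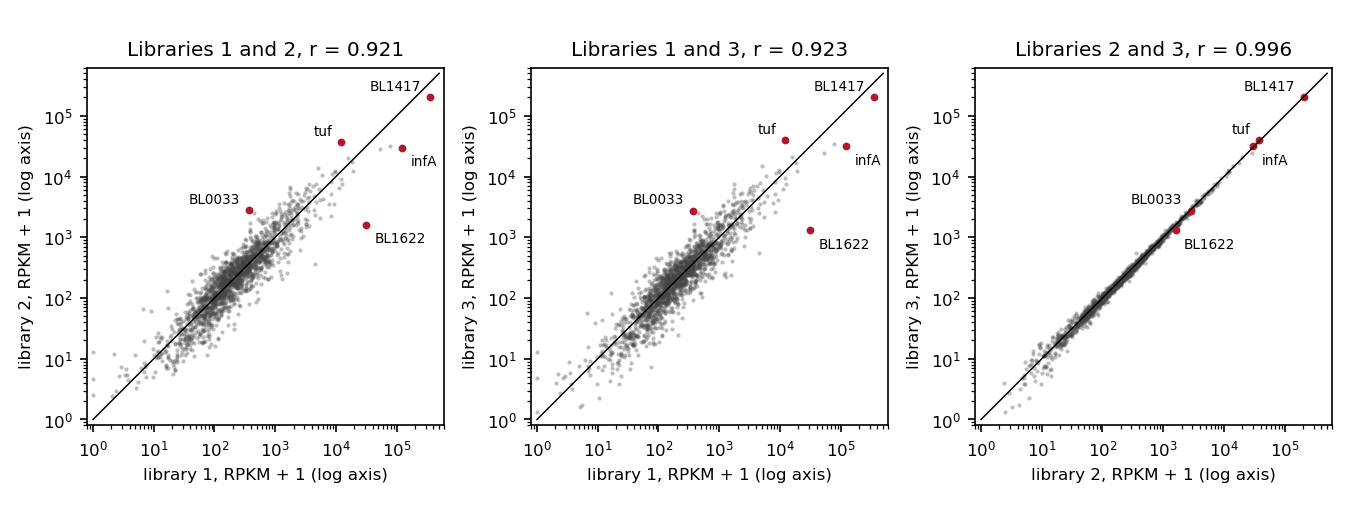
Each point is 1 of the 1726 genes, plotted by its RPKM + 1 in a pair of libraries on log axes, with the line of equality and 5 genes marked in red. Libraries 2 and 3 lie close to the line (r = 0.996), whereas BL1622 and infA lie below it and BL0033 and tuf above it where library 1 is on the horizontal axis (r = 0.921 and 0.923).

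The highest level belonged to a single gene annotated as a hypothetical protein, followed by genes of the translation apparatus. BL1417, a hypothetical protein gene of 567 bases at 328044 to 328610 on the plus strand, had 252871 ± 83335 RPKM (SD, n = 3). It held 19.8% of all reads in library 1 (95% Wilson interval 19.74 to 19.85), 11.6% in library 2 (11.57 to 11.63) and 11.6% in library 3 (11.59 to 11.65), intervals that cover counting error only. It lies between BL1416, which encodes RecX (172 ± 56.1 RPKM), and BL1418 (1427 ± 422 RPKM), on the same strand as recA and secA, which had 126 ± 10.6 and 1340 ± 441 RPKM (SD, n = 3 each). BL1417 exceeded the next highest gene of the same library by 2.84-fold in library 1, 5.48-fold in library 2 and 5.17-fold in library 3. In the related strain of assembly ASM19655v1 the gene of the RNase P RNA, rnpB, lies at this place in the gene order. Whether the reads of BL1417 come from that RNA or from a protein-coding transcript is not settled here, since no sequence was compared.

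**Figure D2:**
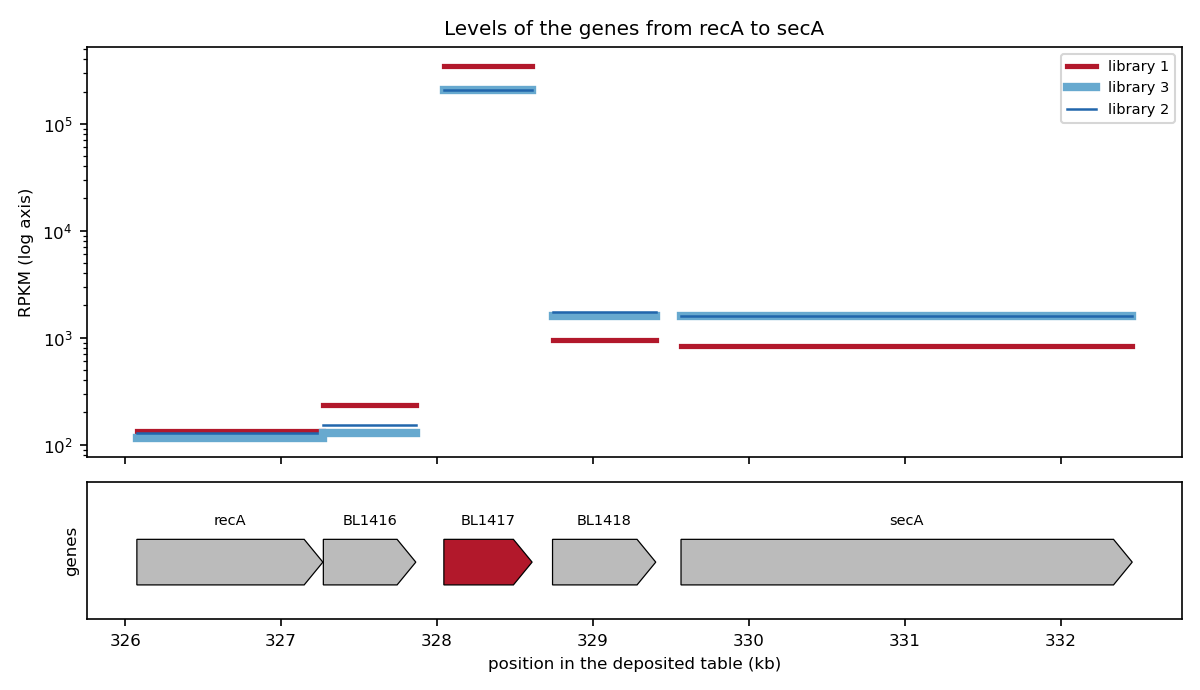
The upper panel gives the RPKM (log axis) of the genes from recA to secA in each of the 3 libraries as horizontal lines over the position of each gene in kb, as the deposited table gives it, and the lower panel shows the genes, all on the plus strand. BL1417 lies between 204583 and 349098 RPKM, while recA and BL1416 lie between 114 and 235 RPKM.

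After BL1417 came, by mean level, infA, encoding translation initiation factor IF-1, with 61684 ± 53169 RPKM, the ribosomal protein genes rpmG (L33) with 47606 ± 25277 RPKM and rpmE (L31) with 35317 ± 15762 RPKM, and tuf, encoding elongation factor Tu, with 29687 ± 15248 RPKM (SD, n = 3 each). Much of this spread lay between library 1 and the others: infA had 123068, 30012 and 31973 RPKM in libraries 1, 2 and 3, and tuf had 12129, 37318 and 39612 RPKM. The order therefore rests on library 1, and in libraries 2 and 3 tuf was above infA, rpmG and rpmE. Of the 20 highest genes, 12 encoded ribosomal proteins, among them rplL, rpsF, rplU, rplM, rplJ, rpsP, rplK, rpsJ, rplW and rpsA, and 3 (BL1417, BL1622 and BL0278) encoded hypothetical proteins. The others were infA, tuf, gpmA (phosphoglyceromutase of glycolysis), ahpC, a peroxide-reducing enzyme with 6748 ± 1747 RPKM, and BL0593, annotated as a septation inhibitor, with 6127 ± 1762 RPKM. BL0278 had 7990 ± 2773 RPKM and lies on the plus strand between lepB and pgi, which are on the minus strand. The same related strain has the ribosomal protein gene rplS at that place in the gene order. BL1622 reached this group through library 1, and 14 of the 20 genes were among the 20 highest of every library.

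The 20 highest genes together held 28.5 ± 4.66% of the reads and the highest 10% of genes, 173 in number, held 56.2 ± 1.66% (SD, n = 3). Without BL1417, an exclusion chosen after its level was seen, the 20 highest remaining genes held 16.7% of the remaining reads. No gene was at 0 in all 3 libraries. In library 1 alone, BL1480, BL1486a and BL1493, a WhiB-type regulator, were listed at 0, where a count of 0 allows up to 2.19, 2.14 and 2.94 RPKM respectively. The lowest gene by mean level was BL1486a, a hypothetical protein gene with 0, 1.51 and 0.336 RPKM in libraries 1, 2 and 3.

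Groups of genes fixed before the data were examined were then compared with all other genes, to ask which functions had transcript levels above or below the rest. Of 20 groups, 7 lay above the other genes and 5 below at a Benjamini-Hochberg adjusted p under 0.05, from two-sided permutation tests with 10000 random lists of the same size. The smallest p these can give is 0.0001, or 0.0004 after adjustment here. The tests describe these libraries, because genes are not replicates. All 12 differences had the same direction in each of the 3 libraries. With rotation of expression along the gene order, which keeps neighbours together, 5 groups passed above the other genes and 5 below. Of those that passed, the adjusted p of the permutation test by rotation was highest for transcriptional regulators (0.0440), nucleotide biosynthesis (0.0373) and sugar transport (0.0373).

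**Figure D3:**
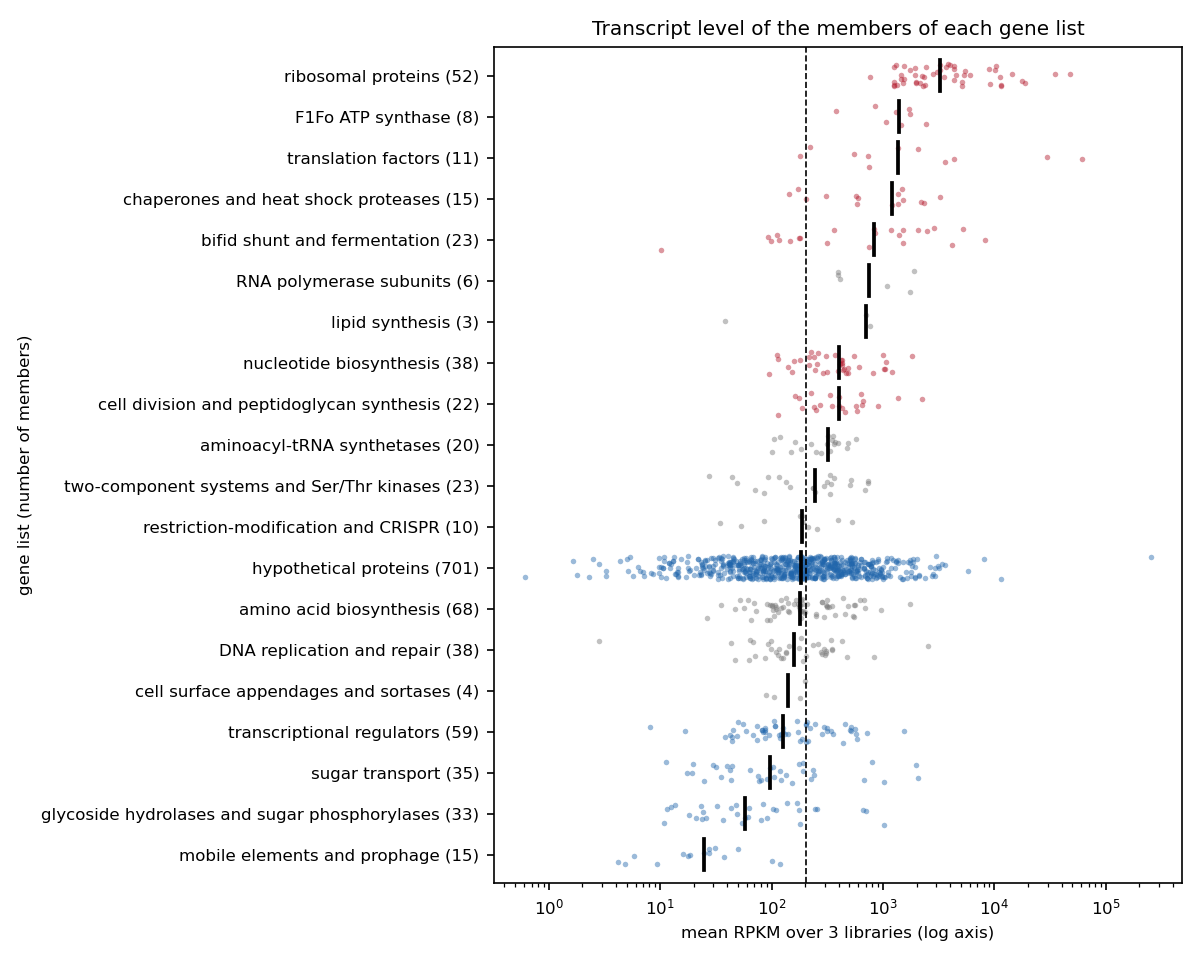
Each point is a gene, plotted by its mean RPKM over the 3 libraries (log axis) in the row of its gene group, with the number of members in parentheses, the group median as a black bar and the median of all 1726 genes (202 RPKM) as a dashed line. Red groups lay above and blue groups below the other genes at an adjusted p under 0.05, and grey groups did not pass. The medians run from 3276 RPKM for ribosomal proteins to 24.9 RPKM for mobile elements and prophage.

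Ribosomal protein genes formed the group with the highest median transcript level. The 52 ribosomal protein genes had a median of 3276 RPKM against 193 RPKM for the other genes, a 16.5-fold difference on the log2(RPKM + 1) scale (log2 difference 3.62, 4.32 and 4.27 in libraries 1, 2 and 3; permutation test, adjusted p = 0.0004). All 52 lay above the median gene in every library, 51 of them were in the highest 10% of genes, and together they held 11.7 ± 1.04% of the reads (SD, n = 3). The lowest of them, rpsT (S20), still had 764 ± 64.2 RPKM. The 11 translation factors lay 6.87-fold above the other genes (permutation test, adjusted p = 0.0004), from infA and tuf at the top, through fusA, encoding elongation factor G, with 3563 ± 747 RPKM, to lepA with 179 ± 12.2 RPKM. The 20 aminoacyl-tRNA synthetase genes, which charge tRNAs, had a median of 318 RPKM and did not pass the test (log2 difference 0.67, permutation test, adjusted p = 0.193). Their highest members were alaS with 572 ± 138 RPKM and hisS with 481 ± 183 RPKM, and their lowest was gltX2 with 101 ± 18.4 RPKM. The 6 RNA polymerase subunit and sigma factor genes had a log2 difference of 1.76 (permutation test, adjusted p = 0.0689), which passed when means replaced medians (adjusted p = 0.0358). Of these, rpoZ and rpoA had 1911 ± 400 and 1728 ± 211 RPKM, and rpoB had 393 ± 13.3 RPKM.

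Genes for the enzymes of the bifid shunt and of fermentation also had transcript levels above the other genes. Their 23 genes had a median of 823 RPKM, a 4.18-fold difference (permutation test, adjusted p = 0.0004), with 14 above the median gene in every library, 6 below it in every library and 3 on different sides. Together they held 3.28%, 5.32% and 5.34% of the reads in libraries 1, 2 and 3. The highest was gpmA, whose 8171 ± 16.8 RPKM barely varied. BL0959, encoding phosphoketolase, the key enzyme of the bifid shunt, had 5195 ± 1227 RPKM, gap, encoding glyceraldehyde 3-phosphate dehydrogenase, had 4181 ± 2137 RPKM, and eno, encoding enolase, had 1517 ± 478 RPKM (SD, n = 3 each). All 3 were lower in library 1 than in the other libraries, gap by the widest margin with 1714, 5419 and 5411 RPKM. Of the genes for lactate dehydrogenase, which makes lactate from pyruvate, ldh2 had 2838 ± 990 RPKM and ldh1 had 92.8 ± 18.0 RPKM, and ldh2 was the higher in every library. The lowest member was BL1726, a pyruvate formate-lyase-activating enzyme, with 10.1 ± 0.646 RPKM.

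**Figure D4:**
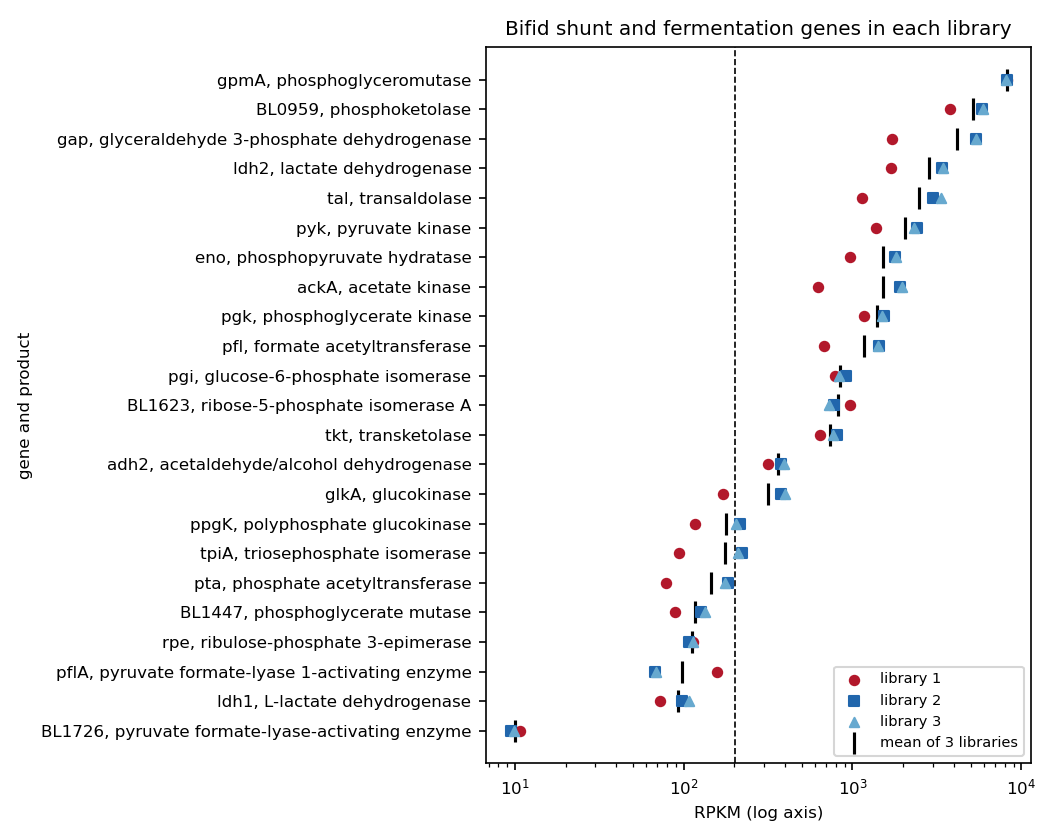
The RPKM (log axis) of the 23 bifid shunt and fermentation genes is shown for each of the 3 libraries, with the mean as a black bar and the median of all genes (202 RPKM) as a dashed line. The genes span from BL1726 at 10.1 RPKM to gpmA at 8171 RPKM, and library 1 lies to the left of libraries 2 and 3 for gap, ldh2, tal and ackA.

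Genes for the uptake and breakdown of sugars lay, as groups, below the other genes. The 35 sugar transport genes had a median of 97.1 RPKM, 0.486 times that of the other genes on the log2(RPKM + 1) scale (permutation test, adjusted p = 0.0060), with 24 below and 5 above the median gene in every library. The exceptions included lacS, a galactoside symporter, with 2054 ± 431 RPKM, and BL0033, whose values differed between libraries as given above, while the sugar permease gene msmG had 11.2 ± 0.860 RPKM. The 33 genes for glycoside hydrolases and sugar phosphorylases, which release sugars from oligosaccharides and plant or host glycans, had a median of 57.2 RPKM, 0.290 times that of the other genes (permutation test, adjusted p = 0.0004). The log2 difference was -1.79, and -1.16 without the lowest 10% of genes (permutation test, adjusted p = 0.0163). Of these, 26 lay below the median gene in every library and 4 above. The highest was lacZ, a beta-galactosidase gene, with 1014 ± 365 RPKM (592, 1221 and 1228 RPKM in libraries 1, 2 and 3). It lies beside lacS on the opposite strand. The arabinosidase gene BL0146 had 708 ± 328 RPKM, and the lowest member, the arabinosidase gene abfA1, had 10.9 ± 1.28 RPKM.

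Chaperones and heat shock proteases, which fold or degrade proteins, had a median of 1208 RPKM over 15 genes, 6.14-fold above the other genes (permutation test, adjusted p = 0.00057). The log2 difference was 2.62, and 1.94 when means replaced medians (permutation test, adjusted p = 0.00175). By library it was 1.59, 2.63 and 2.69 in libraries 1, 2 and 3. The highest was groES with 3222 ± 94.3 RPKM, followed by the small heat shock protein gene BL0576 with 2351 ± 68.1 RPKM. groEL had 1498 ± 506 RPKM and dnaK 1475 ± 798 RPKM, the latter with 558, 1856 and 2010 RPKM in libraries 1, 2 and 3, and the repressor gene hrcA was lowest with 144 ± 54.8 RPKM. The 8 genes of the F1Fo ATP synthase, a membrane enzyme that moves protons, lay 6.93-fold above the other genes (permutation test, adjusted p = 0.0020). They ran from atpG with 2447 ± 802 RPKM and BL0361 (subunit B) with 1757 ± 123 RPKM to atpC with 381 ± 177 RPKM. These genes are neighbours, and their call was lost when expression was rotated along the gene order, which keeps neighbours together (permutation test by rotation, adjusted p = 0.103).

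Nucleotide biosynthesis genes (38) lay 1.97-fold above the other genes (permutation test, adjusted p = 0.0062), with 24 above and 7 below the median gene in every library. By library the log2 difference was 0.52, 1.00 and 0.97 in libraries 1, 2 and 3. The highest were nrdH, a glutaredoxin of ribonucleotide reductase, with 448, 2487 and 2490 RPKM in libraries 1, 2 and 3, and adk, encoding adenylate kinase, with 1197 ± 272 RPKM. The lowest was purT with 94.6 ± 13.7 RPKM. The 22 cell division and peptidoglycan synthesis genes lay 2.06-fold above (permutation test, adjusted p = 0.0322). BL0593, annotated as a septation inhibitor, was not matched to this group. Of the members, ftsH, annotated as a zinc metallopeptidase involved in cell division, had 2226 ± 488 RPKM, and the penicillin-binding protein gene BL1215 had 1354 ± 371 RPKM. The gene ftsZ, encoding the division ring protein, had 910 ± 139 RPKM and ftsK had 113 ± 15.3 RPKM. This call was lost in the permutation test by rotation (adjusted p = 0.103), without the lowest 10% of genes (adjusted p = 0.0602) and against a background without hypothetical proteins (adjusted p = 0.0648).

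Mobile elements and prophage genes were the lowest group. All 15 lay below the median gene in every library, with a median of 24.9 RPKM, 0.130 times that of the other genes (permutation test, adjusted p = 0.0004). Their levels ran from the integrase gene BL1368 with 118 ± 50.8 RPKM and xerC with 101 ± 24.8 RPKM to the integrase gene BL0539 with 4.14 ± 2.22 RPKM. Of these, xerC is annotated as a site-specific tyrosine recombinase and was placed in this group by its symbol alone. Without the lowest 10% of genes, which removes members of this group, the log2 difference was -1.78 against -2.95 with them, and the adjusted p of the permutation test was 0.0640. How reads that map to several places were counted is not given in the sources used here, and copies of these elements were not searched for. The 59 transcriptional regulators had a median of 126 RPKM (log2 difference -0.66, permutation test, adjusted p = 0.0289), with 33 below and 16 above the median gene in every library. They included whiB2 with 2692, 955 and 1012 RPKM in libraries 1, 2 and 3 and BL1529, an IclR-type regulator, with 716 ± 94.0 RPKM, and the call was lost when means replaced medians in the permutation test (adjusted p = 0.0620). The 701 hypothetical protein genes had a median of 182 RPKM against 225 RPKM for the other genes (log2 difference -0.35, permutation test, adjusted p = 0.00057; -0.15, -0.49 and -0.44 in libraries 1, 2 and 3, and -0.59 when means replaced medians), with 330 below the median gene in every library, 269 above it and 43 in the highest 10%.

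The remaining groups did not pass the test. Amino acid biosynthesis (68 genes) had a log2 difference of -0.15 (permutation test, adjusted p = 0.565), with glnA1, encoding glutamine synthetase, highest at 1746 ± 750 RPKM, dapB at 955 ± 310 RPKM and glyA lowest at 26.2 ± 15.6 RPKM. DNA replication and repair (38 genes) had a log2 difference of -0.31 (permutation test, adjusted p = 0.403), from ssb with 2537 ± 695 RPKM and dnaA, the initiator of replication, with 835 ± 338 RPKM to topB with 2.83 ± 0.647 RPKM. In the same group gyrA1, encoding a DNA gyrase subunit, had 262 ± 67.4 RPKM. Two-component systems and Ser/Thr kinases (23 genes) had a log2 difference of 0.31 (permutation test, adjusted p = 0.503), and the response regulator genes BL0005 and BL1000 were highest with 739 ± 176 and 729 ± 164 RPKM, while the sensor kinase gene BL1403 had 27.6 ± 8.39 RPKM. Restriction-modification and CRISPR genes (10) had log2 differences of 0.30, -0.39 and -0.29 in libraries 1, 2 and 3 (permutation test on the mean level, adjusted p = 0.870). Within that group BL1473, a DNA-cytosine methyltransferase gene, had 531 ± 136 RPKM, mrr had 753, 205 and 217 RPKM, and BL1778 had 68.3, 18.6 and 16.9 RPKM in libraries 1, 2 and 3. Lipid synthesis was represented by 3 genes, cdsA with 766 ± 199 RPKM, pgsA with 708 ± 161 RPKM and fas, the fatty acid synthase gene, with 37.9 ± 11.8 RPKM (log2 difference 1.82, permutation test, adjusted p = 0.193; 0.43 when means replaced medians, adjusted p = 0.746). The gene fabG, whose product is listed only as 3-oxoacyl-, was not matched to the lipid synthesis group and had 2389 ± 616 RPKM. The 4 genes for surface appendages and sortases had a log2 difference of -0.57 (permutation test, adjusted p = 0.565), among them BL0675, encoding the fimbrial subunit FimA, with 198 ± 112 RPKM, the sortase gene BL0498 with 178 ± 19.6 RPKM and the pre-pilin peptidase gene BL0486 with 89.1 ± 14.9 RPKM. The nucleoid protein gene hup, fixed as a gene of interest outside these groups, had 4510 ± 909 RPKM.

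Neighbouring genes had similar levels, more so when they shared a strand and lay close together. Spearman's rho of the mean log2(RPKM + 1) across adjacent genes was 0.53 over 1187 same-strand pairs (0.51, 0.53 and 0.52 in libraries 1, 2 and 3) and 0.31 over 532 opposite-strand pairs (0.28, 0.31 and 0.30). Without the lowest 10% of genes rho was 0.42 for same-strand and 0.18 for opposite-strand pairs. Over all genes both values, and their difference of 0.22, had an adjusted p of 0.0001 over these 3 permutation tests, the smallest that 10000 permutations can give. Among same-strand pairs, rho was 0.83 over 308 pairs that overlapped or lay up to 20 bases apart, 0.59 over 333 pairs at 21 to 100 bases, 0.30 over 393 pairs at 101 to 300 bases and 0.31 over 153 pairs further apart. The median difference between neighbours in these classes was 0.73, 1.02, 1.36 and 1.31 on the log2 scale, and these classes were set after the main result was seen. How reads that span neighbouring genes were counted is not given in the sources used here, which bears most on the closest pairs.

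Neither the replication strand of a gene nor its distance to the origin passed its test. With the origin of replication placed at dnaA and the terminus opposite to it, 1129 genes lay on the leading and 594 on the lagging strand, with median levels of 204 and 183 RPKM. The log2 difference was 0.23, 0.17 and 0.14 in libraries 1, 2 and 3, and 0.16 for their mean (permutation test by rotation, two-sided, p = 0.153, adjusted p = 0.306 over 2 tests of position). This result depended on the genes and libraries used: leaving out library 1, 2 or 3 gave unadjusted permutation p-values of 0.217, 0.0482 and 0.0557, and a terminus at the extreme of the cumulative gene strand, chosen after the data were seen, gave a log2 difference of 0.24 with an unadjusted permutation p of 0.0203, whereas without ribosomal proteins and translation factors the difference was 0.062 with an unadjusted permutation p of 0.489. Distance to the origin had a Spearman's rho of -0.03 with level across genes (permutation test by rotation, p = 0.418, adjusted p = 0.418). Coding length had a rho of -0.09 with level across genes, with -0.15, -0.07 and -0.07 in libraries 1, 2 and 3, and a rho of -0.16 with the SD between libraries.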

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

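The alternatives on the terminus, on BL1417, on the weight of libraries 2 and 3, on the lists as first matched and on genes of 300 bases or more were chosen after the data were seen. Of the 20 gene lists, each kept its direction under all alternatives run, except restriction-modification and CRISPR without library 2 (log2 difference 0.0086, permutation test, adjusted p = 0.998), and all 20 kept their side of the threshold under both other pseudocounts, each left-out library, the weighting of libraries 2 and 3 and the lists as first matched; the exceptions, under 4 further alternatives, are given with their adjusted p beside those lists in the report. Size factors from medians of ratios multiply all genes of a library alike, so they cannot move these differences except through the pseudocount and were no test of them. Among lists that did not pass, besides lipid synthesis, the log2 difference moved by over 1.5 times for aminoacyl-tRNA synthetases (0.38 with means, 0.44 without the lowest 10% of genes), two-component systems (0.012 with means, 0.16 without hypothetical proteins in the background), amino acid biosynthesis (-0.37 without the lowest 10% of genes, -0.35 with that background), DNA replication and repair (-0.47 with that background) and restriction-modification and CRISPR (-0.08 in the main test, and from -0.47 with means to 0.0086 without library 2). The number of lists above the other genes ranged from 5 to 8 and of those below from 4 to 5. The correlations of neighbouring genes, their difference, the distance to the origin and the relation of length with level kept their direction and, where tested, their side of the threshold in every alternative run for them. Over the 3 left-out libraries the replication strand difference ranged from 0.16 to 0.21 (log2), the mean Pearson's r between libraries from 0.921 to 0.996 (highest without library 1) and the rho of coding length with the SD between libraries from -0.209 (without library 1) to -0.136. The replication strand difference passed its unadjusted threshold without library 2 (permutation p = 0.0482), with libraries 2 and 3 weighed as 1 (0.21, permutation p = 0.0493) and with the other terminus (0.24, permutation p = 0.0203), and was 0.062 (permutation p = 0.489) without ribosomal proteins and translation factors; the cause was not tested. Without BL1417, the 20 highest genes held 16.7% and the highest 10% of genes 48.8% of the remaining reads, since that gene alone holds a large share.

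No paired analysis was possible because there is 1 group. The tests of the promoter hexamer, ribosome binding site and codon usage and their alternatives were not run because no genome was used here, and a count model for the dispersion between libraries, with its size factors, was planned only for deposited counts and was not fitted. Depth limits the lowest genes, with 19, 3 and 13 genes under 10 reads in libraries 1, 2 and 3.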

Other observations

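The tests on BL1417, on the share taken by a few genes, on gene length and on BL0278 were chosen after the values they bear on were seen, whereas those on genes beside structural RNA genes and on depth were set before. The genes in the next 2 paragraphs were also chosen after their values were seen.

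A run of genes on the minus strand, some annotated as sugar transferases and others as hypothetical proteins, held genes at rank 24 (cps2F) and 35 (cpsF) by mean level. Both were higher in library 1. The glycosyltransferase gene cps2F (1142468 to 1143409) had 9384, 3486 and 4034 RPKM in libraries 1, 2 and 3, and the rhamnosyltransferase gene cpsF beside it had 8247, 2273 and 2585 RPKM. The hypothetical protein genes BL0234 and BL0233 that follow had 5440, 2064 and 2127 RPKM and 4538, 2337 and 2522 RPKM, whereas BL0237, annotated as the galactosyl transferase CpsD on the other side of cpsF, had 727, 515 and 516 RPKM. The nrd genes of ribonucleotide reductase went the other way: nrdI had 385, 1275 and 1336 RPKM, nrdE 150, 545 and 551 RPKM and nrdF 193, 542 and 585 RPKM.

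A pair of solute-binding protein genes lay above the permease genes beside them. The peptide-binding gene dppA2 had 6059 ± 1562 RPKM (SD, n = 3), against 809 ± 182 RPKM for the permease gene dppB and 747 ± 222 RPKM for dppC downstream of it. The sugar-binding gene BL1638 had 1016 ± 554 RPKM, against 121 ± 25.3 and 90.4 ± 8.13 RPKM for the permease genes BL1639 and BL1640. BL0796, encoding choloylglycine hydrolase, an enzyme that splits bile salts, had 2102 ± 244 RPKM in this medium. The ABC transporter genes BL0932 and BL0931 had 4701 ± 2555 and 1318 ± 593 RPKM and lie beside the response regulator gene BL0930, with 314 ± 48.6 RPKM.

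The highest row of the table, BL1417, is annotated as a hypothetical protein gene. Division by its short length is argued against, because it also ranked 1 in every library by reads before division by length. A candidate explanation is that the row counts the RNase P RNA at the place of BL1417: between recA and secA the table lists 3 protein-coding genes, while the related strain of assembly ASM19655v1 has 2 protein-coding genes and rnpB. Whether short rows such as rpmG and rpmE hold reads of a transfer or ribosomal RNA gene beside the row stays open. The 14 symbol-matched genes that lie beside a structural RNA gene in that strain had a median log2 level 0.35 above the 259 not beside them (permutation test, p = 0.584), and 0.065 above (p = 0.928) over the 11 left without rpmG, rpmE and pgi, whose neighbours had been looked at first; neither decides. No biological explanation was tested, since the design has a single condition.

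Library 1 stood apart from libraries 2 and 3 (r = 0.921 and 0.923, against 0.996 between those libraries). Fewer reads in library 1 are argued against: thinned to its 2138109 reads, libraries 2 and 3 still had an r of 0.993, against 0.920 and 0.922 with library 1. A few genes taking a larger share of the reads is argued against as the whole cause, because the log2 ratio of library 1 to library 2 had an SD of 0.80 across genes without the 20 highest, against 0.19 for libraries 2 and 3. Gene length is argued against in the same way, with an SD of 0.79 after a smooth trend in length was removed, although shorter genes were higher in library 1 (rho of the ratio with length -0.18). A separate culture, extraction or sequencing run stays open, since the labels name no difference between the libraries, and no biological explanation was tested.

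BL0278, a hypothetical protein gene among the 20 highest, may hold the reads of rplS, which the table does not list. BL0278 is the gene between lepB and pgi, and in the related strain of assembly ASM19655v1 the 1 protein-coding gene at that place is the ribosomal protein gene rplS. BL0278 lies on the plus strand, whereas lepB and pgi lie on the minus strand. The strand of rplS was not compared, and the use of strand in counting is not given in the sources used here. The link to rplS is a hypothesis from gene order alone, and no sequence was compared.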
